A study of Mus musculus with 12 samples.

How the data were processed

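Kidneys of male mice with X-linked Alport syndrome, 30 weeks old, were measured by bulk messenger RNA sequencing in 12 libraries, 6 from a control diet and 6 from a diet with fisetin (500 ppm). Diet was taken from the sample titles and batch from the labels' batch field, with 3 libraries of each diet in each of 2 batches. Per the labels' protocols, RNA with an integrity number above a set limit was taken and libraries were made with the KAPA mRNA HyperPrep kit. The genotype field of the labels reads HET although the design text describes males, in which an X-linked gene has a single copy, so no allele status is used here. Libraries are named by diet and by a number given in accession order, which pairs nothing.

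The submitters' processing notes name fastp, STAR, featureCounts and DESeq2 and the builds GRCm38 and mm10, with no versions. The annotation release and the counting settings are not given in the sources used here. The deposited table holds estimated counts, TPM and FPKM for each library, per the file headers. The estimated counts are not scaled for depth, and 13.91% of the deposited count values above 0 were not whole (tolerance 1e-06), so they were rounded before testing. The TPM values were scaled to a fixed total of transcripts, and the FPKM values for transcript length and sequencing depth, by the authors. All 36 value columns were matched to a sample by name. Of 55487 genes, 25636 were never above 0, and 55141 identifiers were matched to the reference annotation (GENCODE M21 on GRCm38, 55450 genes), which gave symbols and coordinates.

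Total counts per library were 16310214 to 24451821. Libraries were compared in 66 pairs over 16473 genes with a mean count of at least 20. Their mean squared difference was 6.996 to 104.8 times that of counting noise, so no library looked like a copy of another.

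Genes were tested in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr by diet (minimum count 10), 17890 in all, were scaled with TMM, fitted with glmQLFit (robust) with terms for batch and diet, and tested with glmQLFTest, two-sided. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The interaction of diet with batch and the batch term were tested the same way. DESeq2 1.42.0 (Wald test) was run as an alternative, and adjusted p-values it gave as NA were kept so. Standard errors of edgeR log2 fold changes were taken from the fold change and the F statistic.

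Before the data were examined, 57 gene lists of pathways, cell type markers and possible stray tissue were fixed, of which 55 were tested. The adrenal list had under 3 members past the filter, and the sex-linked list served as a label check. Lists were tested with voom weights and fry of limma 3.58.1, and by camera with a preset correlation of 0.01 and with an estimated one. A list's score was the mean log2 CPM of its members (prior count 2), and the fisetin minus control difference within batch was tested over all 400 arrangements of diet labels within batches, exact and two-sided, where the smallest p is 0.005. For any list score to pass over 55 lists, several lists would have to come near that smallest p together, so not passing by score says little. Several lists share members, for example 7 of the 20 p53 targets with other lists. Members of a list were also adjusted over the list alone. Members can move together, with an estimated correlation as high as 0.937 for B cell markers, so counts of members by sign are not independent.

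Genes named in the text follow a rule fixed before the data were examined. It takes per direction up to 12 genes past the threshold with a mean log2 CPM of at least 0 and, where fewer than 5 pass, the 5 with the smallest p. It adds fixed kidney genes, the 4 members with the smallest p in each list that passes, and 2 in each other list described. Further members, among them Irf7, Oas3, Ifih1, Tap1, Nlrc5, Aqp2, Aqp3, Avpr2, Scnn1g, Scnn1b, Hsd11b2, Mdm2, Plk2, Eda2r, Ephx1, Gstm2, Nfe2l2, Trim30a, H2-K1, Dbp and Nr1d2, were named after their values were seen. So were Gpnmb, Hmox1, Gclc, Gclm, Lmnb1, Bmi1 and Ighm. Results on some genes that the rule names are withheld and not reported here.

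The steps were tested on simulated counts drawn from the means and library sizes of these libraries, with the dispersions that edgeR estimated. There were 3 simulations (17721 genes tested on average), with 200 genes in each changed by known folds, and the values below are means. edgeR recovered 22.67% at 1.3-fold, 54.67% at 1.5-fold, 77.33% at 2-fold and 92% at 3-fold, with 4.857% of its calls false. DESeq2 recovered 38.67%, 70%, 81.33% and 95.33% with 21.74% false, and limma-voom with quality weights 22.67%, 55.33%, 76.67% and 92% with 4.348% false. In 20 simulations fry called an interferon list raised 1.3-fold in 100% and an unchanged one in 0%. Each gene was drawn independently, so the simulations leave out genes that move together, and their rates may not hold for these kidneys. The counts followed edgeR's own dispersions, so the simulations do not rank the tools fairly.

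Alternatives were DESeq2, limma-voom with sample quality weights, DESeq2 size factors, total count scaling, no count filter, and a stricter filter (10 counts in 6 libraries and a mean CPM of 1). Others were no batch term, each batch alone, surrogate variables (sva 3.50.0), no robust estimation, and limma on log2(TPM + 1), log2(TPM + 0.1) and log2(FPKM + 1), with a filter of 0.1 TPM in 6 libraries. Of these, log2(TPM + 1) alone was also run without that filter. Each library was left out in turn. Correlations across the 12 kidneys were tested with 100000 permutations. Regroupings of the libraries were drawn 100 at a time from the 462 possible, leaving out the regrouping that follows batch, with which the model could not be fitted. Genes of near-identical families and overlapping genes are uncertain, since the counting rule for shared reads is not given in the sources used here. No healthy kidney, protein or phosphorylation data were analysed here.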

Results

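Messenger RNA was sequenced from whole kidneys of male mice with X-linked Alport syndrome, an inherited kidney disease of the type IV collagen network in the glomerular basement membrane. The mice, of the B6 background, were 30 weeks old and had been fed a control diet or a diet with 500 ppm of fisetin, a flavonol found in fruit. There were 6 control and 6 fisetin libraries, and each of the 2 batches named in the labels held 3 of each diet. Total counts per library ran from 18638748 to 22396857 with the control diet (n = 6) and from 16310214 to 24451821 with fisetin (n = 6). Of 55487 genes in the table, 17890 passed the count filter and were tested. The labels do not say that each library came from its own animal, so the p-values measure the spread between these samples. No library from a healthy mouse was used here, so every value below compares diseased kidneys with diseased kidneys.

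Col4a5, the X-linked collagen chain gene that the labels name, was counted in all 12 libraries, between 18.82 and 25.56 CPM, counts scaled to library size. Its mean was 23.31 ± 0.69 CPM (SD, n = 6) with the control diet and 22.2 ± 2.49 CPM (n = 6) with fisetin. A message level does not show which variant is present, and there was no unaffected kidney to set it against. The Y-linked gene Ddx3y had between 924 and 1341 counts per library and Xist, the transcript of an inactive X chromosome, between 3 and 13.

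The first comparison asked what fisetin in the diet did to the kidney transcriptome, with mTOR signalling, which the series title names as a modifier and target of the disease, as a point of interest. Interferon-response genes had higher means in the fisetin kidneys and markers of collecting duct principal cells, water and sodium channel genes among them, had lower means, each by a modest amount. Neither list passed over the 55 tested by fry or by score (adjusted p = 0.138 by score for both, and adjusted p = 0.726 with an estimated correlation). By score a pass was nearly out of reach, since several lists would have to come near the smallest possible p together. Immune cell markers had a mean 0.62 log2 higher (exact permutation p = 0.1) and those of other tubule segments differed by -0.32 in the same kidneys. The mean of 38 interferon-response genes was 4.37 ± 0.16 log2 CPM (SD, n = 6) with fisetin against 3.98 ± 0.16 (n = 6) with the control diet, a 1.31-fold difference. The mean of 16 principal cell markers was 4.64 ± 0.30 log2 CPM against 5.12 ± 0.12, or 0.719 of the control level. Several targets of p53 and of NRF2, the regulator of antioxidant and detoxifying enzymes, were also higher, and the clock genes Npas2 and Cry1 were lower while Dbp and Nr1d2 were higher. No single gene passed the threshold over all genes in the main test, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, where the smallest adjusted p was 0.145 and 2608 genes had an unadjusted p under 0.05 (1473 higher and 1135 lower, with 894 given by chance).

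By DESeq2, 153 genes passed (91 higher and 62 lower), 2817 had an unadjusted p under 0.05, and 1403 were given no adjusted p. limma-voom with sample quality weights called 2390 genes (1156 higher and 1234 lower), and a fit with 2 surrogate variables called 9. The edgeR count was 70 without fisetin 6 (44 higher and 26 lower) and 1 without fisetin 4, and 0 without each other library in turn. Without fisetin 6 DESeq2 called 1713 genes, without control 1 it called 614, and without fisetin 5 it called 63. In simulated libraries with known changes, edgeR recovered 22.67% of 1.3-fold and 77.33% of 2-fold changes with 4.857% of its calls false, and DESeq2 recovered 38.67% and 81.33% with 21.74% false. Each simulated gene was drawn independently, whereas interferon-response genes had an estimated correlation of 0.412 in these kidneys, so those rates may not hold here. The draws also used dispersions that edgeR estimated, so they do not rank DESeq2 fairly against edgeR.

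**Figure D1:**
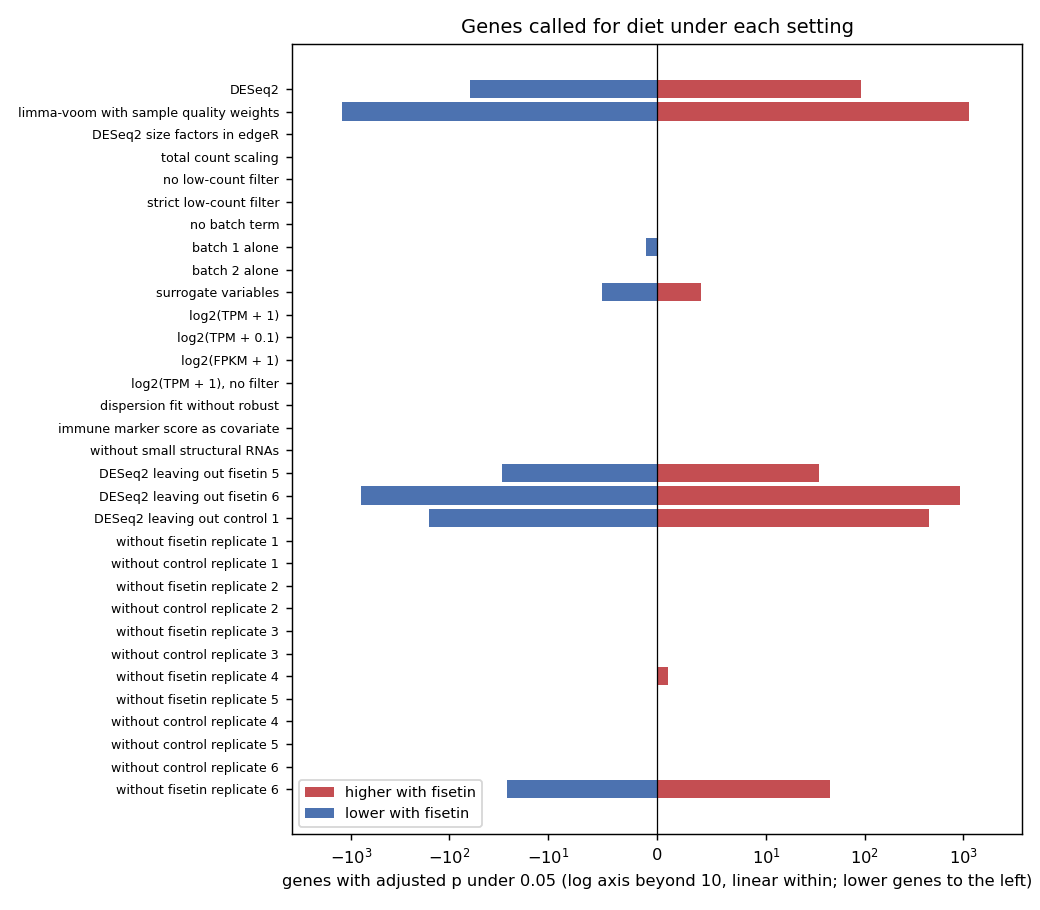
Genes with an adjusted p under 0.05 for diet under each alternative, with genes higher with fisetin to the right and lower to the left, on an axis that is linear within 10 and logarithmic beyond. DESeq2 called 153 and limma-voom with quality weights 2390, while most edgeR settings called 0.

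The genes with the smallest p, none of which passed by edgeR and all of which passed by DESeq2, held several with known roles in the kidney. Gsta2, a glutathione transferase on chromosome 9 (78331018 to 78355788, GRCm38), had 309 ± 41.9 CPM with fisetin against 219.5 ± 25.3 with the control diet (SD, n = 6 each), a log2 fold change of 0.50 ± 0.08 (SE). Ccng1, a p53 target on chromosome 11 (40748552 to 40755311), had 212.4 ± 12.6 against 158.8 ± 18.6 CPM, with a log2 fold change of 0.42 ± 0.07. Ifi206, an interferon-inducible gene on chromosome 1 (173468485 to 173491041), had a log2 fold change of 0.78 ± 0.14. Spc25, a kinetochore gene on chromosome 2 (69193895 to 69206194), and Gprin3 on chromosome 6 (59347226 to 59426294) had 0.40 ± 0.07 and 0.46 ± 0.08. On the lower side were Ptges, the prostaglandin E synthase gene on chromosome 2 (30889471 to 30929863), at -0.56 ± 0.09, and Ptger1, which encodes a prostaglandin E receptor, on chromosome 8 (83666678 to 83672753), at -0.60 ± 0.10. Slitrk1 on chromosome 14 (108908800 to 108914158) stood at -1.29 ± 0.20 from a low level of 2.58 CPM in control kidneys, and Galnt2 on chromosome 8 (124231391 to 124345724) at -0.42 ± 0.07. Npas2, a clock transcription factor on chromosome 1 (39193731 to 39363236), had 15.4 ± 3.26 against 25.6 ± 4.21 CPM, a log2 fold change of -0.73 ± 0.13. Each of these 10 genes had an edgeR adjusted p of 0.145 and a DESeq2 adjusted p of 4.41e-05 to 0.000639, and lay beyond the control mean in its direction in 6 of 6 fisetin libraries. They were picked by their p in these same libraries, so the 6 of 6 follows in part from the choice and is no separate support. Gsta2 and Ifi206 belong to families of near-identical genes, so reads may be divided among relatives and their values are uncertain.

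Interferon-response genes, which cells switch on when they sense viral or self nucleic acid, were higher with fisetin in 38 of 38 tested members, and 29 passed adjusted over the list alone, against 0 over all genes by edgeR and 10 by DESeq2. Among them were the sensor Ifih1 (log2 fold change 0.33 ± 0.07), the transcription factor Irf7 (0.51 ± 0.13), the antiviral enzyme Oas3 (0.70 ± 0.18), and Ifit2 (0.45 ± 0.09), Iigp1 (0.61 ± 0.13) and Trim30a (0.49 ± 0.11). The list's score differed by 0.39 log2 (exact permutation p = 0.01, two-sided; adjusted p = 0.138 over 55 lists), by 0.36 in batch 1 and 0.42 in batch 2. By fry, limma's rotation test of whether a list's genes move on balance one way, the adjusted p was 0.0866. It was 0.0251 for change in either direction, and neither form compares the list with other genes. The preset-correlation set test camera called the list, with an adjusted p = 0.726 with an estimated correlation. The mean score of macrophage, dendritic, T, NK and B cell markers was 0.62 log2 higher in the same fisetin kidneys (exact permutation p = 0.1). The count of 29 was 0 in batch 1 alone, 14 in batch 2 alone and 10 with that immune score as a covariate.

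Antigen presentation genes were higher in 20 of 20 members, and 9 passed adjusted over the list alone, against 0 over all genes by edgeR and 1 by DESeq2. They included B2m, the light chain of class I molecules (0.47 ± 0.13), the peptide transporter gene Tap1 (0.58 ± 0.19), Nlrc5, the class I transactivator (0.62 ± 0.21), and Ciita, the class II transactivator (0.47 ± 0.15). The score was 7.03 ± 0.28 log2 CPM with fisetin against 6.66 ± 0.25 (SD, n = 6 each; exact permutation p = 0.055), and differed by 0.26 in batch 1 and 0.48 in batch 2. The fry adjusted p was 0.374, and camera gave an adjusted p = 0.733 with an estimated correlation. Control 1 had the highest control score, and 19 members passed without it, while 0 passed without each of fisetin 1, 4 and 5 and control 2, 3, 4, 5 and 6, in batch 1 alone, or with the immune score as a covariate, and 1 in batch 2 alone. Class I genes such as H2-Q4 and H2-K1 share sequence, and their separate values are uncertain. The list's members had an estimated correlation of 0.866, so their shared direction is not independent agreement.

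**Figure D2:**
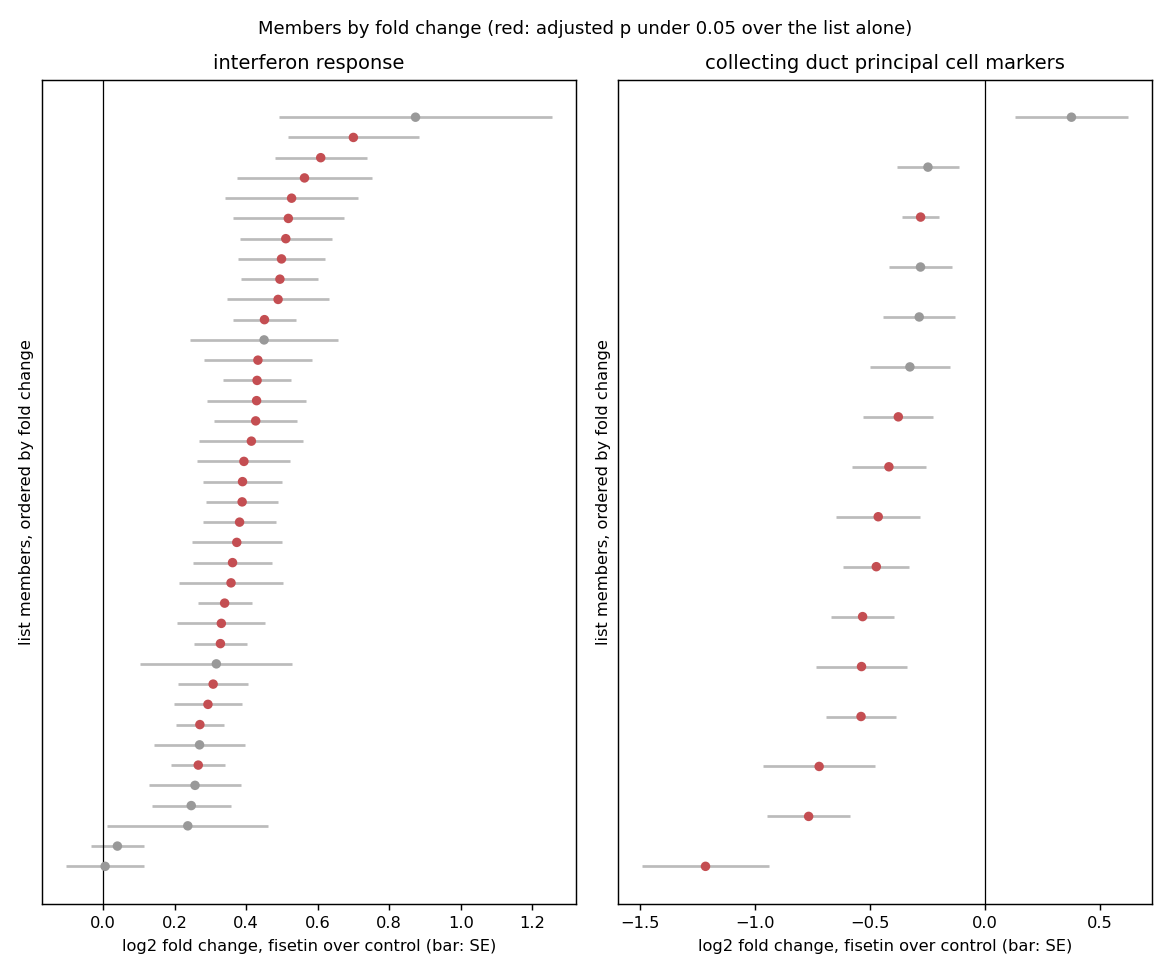
Log2 fold change of each tested member, fisetin over control, with its standard error as a bar, for the interferon response (left) and principal cell markers (right), and red points for members that passed adjusted over the list alone. All 38 interferon members lie above 0 and 15 of 16 principal cell markers lie below it.

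Collecting duct principal cell markers were lower with fisetin in 15 of 16 members, and 11 passed adjusted over the list alone, against 0 over all genes by edgeR and 3 by DESeq2. The vasopressin-regulated water channel gene Aqp2 had 94.3 ± 34.9 CPM with fisetin against 155.8 ± 26.3 (SD, n = 6 each), a log2 fold change of -0.72 ± 0.24. The basolateral water channels Aqp3 (-0.46 ± 0.18) and Aqp4 (-1.21 ± 0.28), the vasopressin receptor gene Avpr2 (-0.54 ± 0.20) and the sodium channel subunits Scnn1g (-0.47 ± 0.14) and Scnn1b (-0.38 ± 0.15) were lower too. So were Elf5, a transcription factor of principal cells (-0.77 ± 0.18), and Hsd11b2, which inactivates glucocorticoids (-0.42 ± 0.16). The score differed by -0.48 log2 (exact permutation p = 0.005, the smallest that 400 arrangements can give; adjusted p = 0.138), by -0.36 in batch 1 and -0.60 in batch 2. The fry adjusted p was 0.128, and camera called the list with the preset correlation but had an adjusted p = 0.726 with an estimated correlation. Other tubule markers had lower means as well, and the average of the proximal tubule, thick limb and distal tubule scores differed by -0.32 (exact permutation p = 0.125). The count of 11 was 6 without fisetin 1, control 3 or control 6, 0 within either batch alone, 3 with the immune score as a covariate and 1 on log2(TPM + 1). The small structural 7SL RNA held from 40.34% (fisetin 5) to 53.1% (control 1) of all TPM, so TPM values of other genes depend on it.

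Thin limb markers had a score of 4.57 ± 0.06 log2 CPM with fisetin and 4.77 ± 0.10 with the control diet (SD, n = 6 each; exact permutation p = 0.01; adjusted p = 0.138), with differences of -0.13 and -0.27 in batches 1 and 2. The urea transporter gene Slc14a2 (-0.46 ± 0.12) and the aldose reductase gene Akr1b3 (-0.34 ± 0.09), both part of how the inner medulla handles a concentrated environment, passed adjusted over the list alone, against 0 over all genes by edgeR and 1 by DESeq2. The camera call had an adjusted p = 0.726 with an estimated correlation. Marker scores of other segments differed by -0.28 for proximal tubule segments 1 and 2, -0.46 for segment 3, -0.24 for the thick ascending limb, -0.30 for the distal convoluted and connecting tubule and -0.18 for intercalated cells, with exact permutation p between 0.1 and 0.345. Of their members, 22 of 24, 16 of 17, 15 of 16, 13 of 14 and 13 of 19 had negative fold changes, and 0 passed adjusted over each list alone. Without fisetin 5 the differences of the 5 lists were -0.14, -0.28, -0.12, -0.16 and -0.05. Without fisetin 6 those of proximal tubule segments 1 and 2, segment 3, the distal tubule and intercalated cells were -0.42, -0.63, -0.45 and -0.32. That of the thick ascending limb was -0.34 without control 1. Examples of members were the organic anion transporter genes Slc22a8 (-0.71 ± 0.28) and Slc22a13 (-0.58 ± 0.20) and the anion exchanger gene Slc4a9 (-0.44 ± 0.15), whereas Pck1, of gluconeogenesis, was at 0.77 ± 0.21 and was called over all genes by DESeq2.

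**Figure D3:**
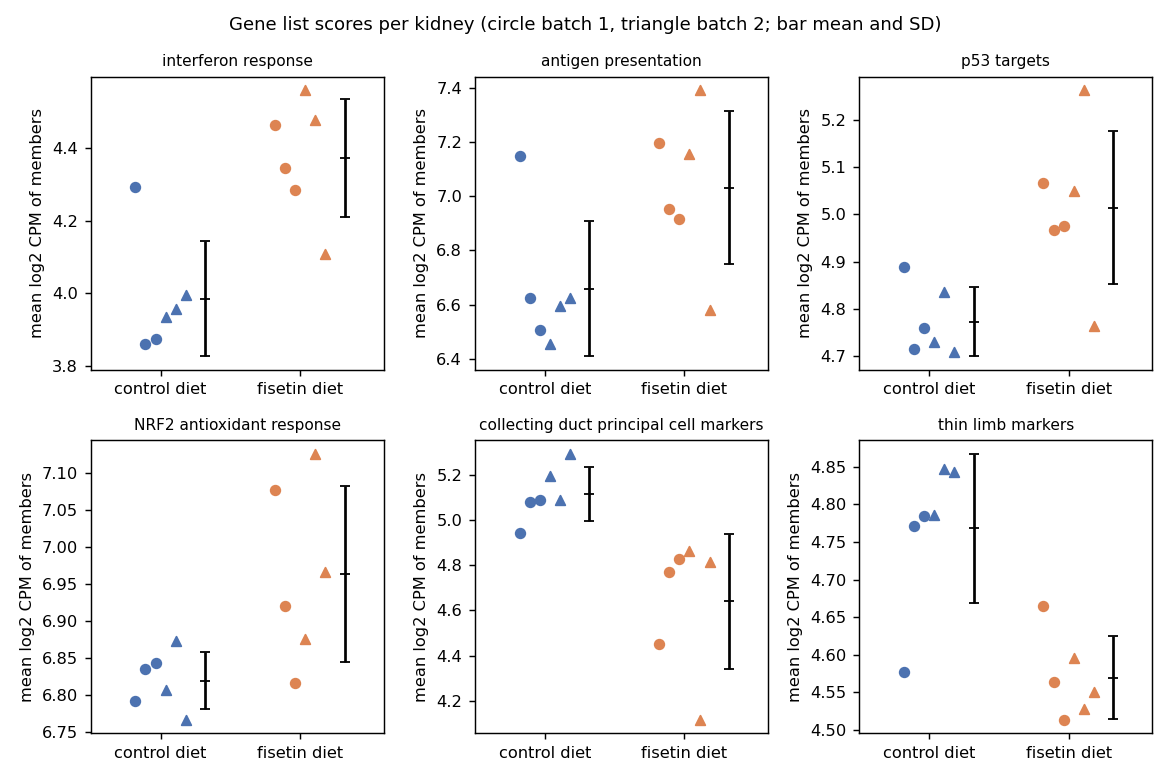
Mean log2 CPM of each list's members per kidney for 6 lists, with control kidneys at left and fisetin at right, circles for batch 1, triangles for batch 2, and bars for mean and SD (n = 6). All 6 fisetin kidneys lie below all 6 control kidneys for principal cell markers, and control 1 and fisetin 6 lie toward the other diet's kidneys for the interferon response.

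p53 targets had 17 of 20 members with positive fold changes. Adjusted over the list alone, 6 were higher and 1 lower, against 0 over all genes by edgeR and 3 by DESeq2. The higher ones were Ccng1, Zmat3 (0.27 ± 0.05), the death receptor gene Eda2r (1.19 ± 0.26), the BCL2-family gene Pmaip1 (0.54 ± 0.15), Plk2 (0.27 ± 0.08) and Mdm2, the ligase that degrades p53 (0.14 ± 0.05). Sesn2, a leucine sensor that restrains mTOR complex 1, was lower (-0.41 ± 0.11). Cdkn1a, the cell cycle inhibitor p21, did not pass, with 29.2 ± 7.06 CPM against 21.8 ± 3.64 (SD, n = 6 each). The score differed by 0.24 log2 (exact permutation p = 0.01; adjusted p = 0.138), by 0.21 and 0.27 in batches 1 and 2. The fry adjusted p was 0.128 on balance and 0.0402 for either direction, and camera gave an adjusted p = 0.726 with an estimated correlation. The count of 7 was 11 without fisetin 6, 0 in batch 2 alone and 3 with the immune score as a covariate.

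Among 30 NRF2 targets and partners, 5 were higher and 1 lower adjusted over the list alone, against 0 over all genes by edgeR and 3 by DESeq2. Higher were Gsta2, Gstm1 (0.43 ± 0.09), the epoxide hydrolase gene Ephx1 (0.85 ± 0.18), the quinone reductase gene Nqo1 (0.33 ± 0.09) and Nfe2l2, which encodes NRF2 itself (0.15 ± 0.05), and Gstm2 was lower (-0.22 ± 0.07). Other classic targets did not pass, such as Hmox1 (0.10 ± 0.08), Gclc (-0.12 ± 0.07) and Gclm (-0.11 ± 0.10). The score differed by 0.14 log2 (exact permutation p = 0.025; adjusted p = 0.275), by 0.12 and 0.17 in batches 1 and 2, with a fry adjusted p of 0.258 and an adjusted p = 0.733 with an estimated correlation. The count of 6 was 3 without control 6 and in batch 1 alone, and 0 in batch 2 alone. Of 12 aryl hydrocarbon receptor genes, which flavonoids can bind to activate, Nqo1 alone passed adjusted over the list alone (0 over all genes by either tool), and Cyp1b1 was at 0.26 ± 0.10. The drug and flavonoid conjugation list had a score difference of -0.10 (exact permutation p = 0.365) and 0 of 39 members past the list's own adjustment, with Ugt1a2 at 1.59 ± 0.46 and Ugt1a1, which shares exons with it, at 1.31 ± 0.44.

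Circadian clock genes moved both ways. Adjusted over the list alone, Npas2 and Cry1 (-0.31 ± 0.09), whose messages follow the activator arm of the clock, were lower, and the output gene Dbp (0.63 ± 0.20) and the repressor gene Nr1d2 (0.29 ± 0.10) were higher, 4 of 19 members against 0 over all genes by edgeR and 1 by DESeq2. The fry adjusted p was 0.00829 for change in either direction and 0.855 on balance, and the score differed by 0.05 (exact permutation p = 0.255; 0.10 and -0.01 in batches 1 and 2). The count of 4 was 10 without fisetin 6. It was 1 without each of fisetin 2, 3 and 4 and control 2, 5 and 6 and in batch 1 alone, and 0 in batch 2 alone.

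Components of the mTOR pathway, the kinase network that couples growth to nutrients, showed no shared shift in message. Of 61 members, 25 had positive and 36 negative fold changes, 0 passed adjusted over the list alone and 0 over all genes by edgeR or DESeq2, and 9 had an unadjusted p under 0.05. Mtor itself had 269.7 ± 38.8 CPM with fisetin and 303.4 ± 54.4 with the control diet (SD, n = 6 each; log2 fold change -0.16 ± 0.12, adjusted p = 0.497). Sesn2 was among the members with the smallest p. The score was 5.59 ± 0.04 against 5.62 ± 0.04 log2 CPM (exact permutation p = 0.21; -0.02 and -0.03 in batches 1 and 2; positive at 0.02 with total count scaling), and the fry adjusted p was 0.613. mTOR acts by phosphorylation, which message levels do not measure.

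Processes that mTOR complex 1 steers at the message level were described by further lists. The sterol synthesis score differed by -0.02 (exact permutation p = 0.805), with Mvk at -0.19 ± 0.09. In fatty acid synthesis, the desaturase genes Fads2 (-0.33 ± 0.06) and Scd2 (-0.27 ± 0.08) passed adjusted over the list alone, against 0 over all genes by edgeR and 1 by DESeq2. That list's mean log2 fold change was 0.06 and its median 0.02, while fry's direction was down and the score differed by -0.06 (exact permutation p = 0.81; -0.25 and 0.12 in batches 1 and 2). Its score was highest in fisetin 5 (7.35) and control 3 (7.14) and lowest in fisetin 3 and 4 (6.17 each). The adipocyte marker score was also highest (5.55 and 5.35) and lowest (2.01 and 1.79) in these kidneys. The fatty acid score may therefore follow fat taken with the kidney, which was not tested. Glycolysis differed by -0.03 (p = 0.455, exact), with the glucose transporter gene Slc2a1 at -0.23 ± 0.06 and Hk1 at -0.15 ± 0.06. The ATF4 amino acid response differed by 0.05 (p = 0.68, exact), with Sesn2 low and Gdf15 at 0.40 ± 0.15. Lysosome and autophagy genes differed by -0.003 (p = 0.895, exact; mean log2 fold change 0.002, median -0.03), with Naglu at -0.18 ± 0.05 and Hexa at 0.25 ± 0.09. Cytosolic ribosomal protein genes differed by 0.03 (p = 0.46, exact), with Rps3a1 at 0.16 ± 0.06 and Rps4x at 0.15 ± 0.07.

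Mitochondrial genes had lower means without passing by fry or by score. Nuclear-encoded respiratory chain genes had negative fold changes in 70 of 72 members, with Ndufb2 at -0.22 ± 0.08 and Ndufa3 at -0.23 ± 0.10, and the score was 6.71 ± 0.21 against 6.87 ± 0.15 log2 CPM (SD, n = 6 each; exact permutation p = 0.135; -0.15 and -0.17 in batches 1 and 2; -0.09 without fisetin 5). The respiratory chain members had an estimated correlation of 0.87, so their signs are not independent. Proximal tubule markers of segments 1 and 2 differed by -0.28 in the same kidneys. The adjusted p was 0.514 by fry and 4.82e-11 by camera with its preset correlation, with an adjusted p = 0.733 with an estimated correlation. Mitochondrially encoded messages differed by -0.08 (exact permutation p = 0.63), with mt-Atp6 at -0.21 ± 0.14 and mt-Cytb at -0.12 ± 0.16. Among PPAR-alpha targets and fatty acid oxidation genes, 1 of 27, the hydroxylase gene Cyp4a14 (0.64 ± 0.14), passed adjusted over the list alone, against 0 over all genes by edgeR and 1 by DESeq2. The list's score differed by -0.02 (exact permutation p = 0.84).

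Lists of scarring, of the filter, of tubular injury and of vessels did not pass by fry or by score, and 0 of their members passed adjusted over each list alone. The score of 37 interstitial matrix and myofibroblast genes was 6.60 ± 0.21 log2 CPM with fisetin and 6.57 ± 0.19 with the control diet (SD, n = 6 each; exact permutation p = 0.815; -0.06 and 0.12 in batches 1 and 2). The fibrillar collagen gene Col1a1 was at -0.02 ± 0.15 (positive with total count scaling), Fn1 at 0.09 ± 0.14, Acta2 at -0.21 ± 0.13, Thbs2 at 0.47 ± 0.13 and Vcan at -0.39 ± 0.12. Basement membrane genes differed by -0.02 (exact permutation p = 0.54; positive with total count scaling), and the partner chains of Col4a5, Col4a3 and Col4a4, were at -0.23 ± 0.10 and -0.31 ± 0.11 (adjusted p = 0.319 and 0.290). Podocyte markers differed by -0.02 (exact permutation p = 0.77; positive with total count scaling), with the slit diaphragm gene Nphs1 at -0.15 ± 0.16 and Tcf21 at 0.22 ± 0.09. Tubular injury genes differed by 0.09 (exact permutation p = 0.57), with the injury markers Havcr1 at -0.10 ± 0.19 and Lcn2 at -0.14 ± 0.20 and the chemokine gene Cxcl1 at 0.52 ± 0.26. Endothelial markers differed by -0.08 (exact permutation p = 0.26; Cd34 -0.14 ± 0.05, Esam -0.18 ± 0.07), and camera with its preset correlation called that list (adjusted p = 0.00837), with an adjusted p = 0.733 with an estimated correlation. Mesangial and juxtaglomerular markers differed by -0.06 (exact permutation p = 0.48; median 0.02 and mean -0.04; Ntn1 -0.31 ± 0.12, Gata3 -0.28 ± 0.14). Smooth muscle and pericyte markers differed by -0.09 (exact permutation p = 0.435; Actg2 -0.94 ± 0.31, Smtn -0.15 ± 0.06).

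Genes of cell senescence, which fisetin is used to target in other settings, had positive values without passing by fry or by score. In the arrest and marker list 12 of 13 members had positive fold changes, with Gdf15 and Gpnmb (1.12 ± 0.42) among them and the lysosomal galactosidase gene Glb1 at -0.24 ± 0.09. The positive members also include Lmnb1 and Bmi1, whose rise is not a sign of senescence. The list's count and score therefore mix markers of both directions. Its score was 4.20 ± 0.20 against 3.99 ± 0.15 log2 CPM (SD, n = 6 each; exact permutation p = 0.075; 0.19 and 0.22 in batches 1 and 2), and 0 members passed adjusted over the list alone. Cdkn2a, which encodes the arrest protein p16, had 2 to 12 counts per library and was too low to test. Senescence-associated secretory genes differed by 0.14 (exact permutation p = 0.24), with Igfbp4 at -0.36 ± 0.11 and Cxcl2 at 0.61 ± 0.21. In the BCL2 family, Bad, a promoter of apoptosis, was lower (-0.24 ± 0.05) and Pmaip1, another, was higher, both adjusted over the list alone (0 over all genes by edgeR, 1 by DESeq2). That list's score differed by 0.14 (exact permutation p = 0.14).

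Immune cell markers had higher means with fisetin and a wide spread within each diet, and no list passed by fry or by score. Macrophage markers were positive in 26 of 26 members (Mpeg1 0.52 ± 0.17, Aif1 0.57 ± 0.20), with a score of 5.03 ± 0.45 against 4.64 ± 0.29 log2 CPM (SD, n = 6 each; exact permutation p = 0.095; 0.35 and 0.45 in batches 1 and 2). T and NK cell markers were positive in 24 of 24 (Il7r 1.06 ± 0.32, Cd6 0.99 ± 0.36), and differed by 0.71 (exact permutation p = 0.095; 0.55 and 0.87). B cell markers were positive in 14 of 14 (Bank1 1.19 ± 0.63, Cd37 0.91 ± 0.50) and differed by 1.12 (exact permutation p = 0.145; 0.94 and 1.31). Bank1 and Cd37 turned negative with the immune score, of which both are part, as a covariate. Estimated correlations among members were 0.851 for macrophage, 0.804 for T and NK cell and 0.937 for B cell markers. The signs within each of these lists are therefore not independent. Plasma cell and immunoglobulin genes differed by 1.44 (exact permutation p = 0.165; Iglc1 2.84 ± 1.28, Prdm1 0.64 ± 0.35). Dendritic cell markers differed by 0.26 (exact permutation p = 0.06; Flt3 0.51 ± 0.16, Clec9a 0.36 ± 0.12), chemokines and cytokines by 0.30 (exact permutation p = 0.19; Cxcl2, Ccl12 0.52 ± 0.19) and complement, positive in 14 of 19, by 0.16 (exact permutation p = 0.195; its members with the smallest p were negative, C4b -0.26 ± 0.08, Cfb -0.39 ± 0.13). Lipid-associated macrophage genes differed by 0.22 (exact permutation p = 0.095; Fabp5 0.78 ± 0.29, Ctsb 0.16 ± 0.06) and the 3 tested neutrophil and mast cell markers by 0.15 (exact permutation p = 0.335; Cxcr2 0.43 ± 0.24, Csf3r 0.34 ± 0.20). Without control 2 the plasma cell difference was 0.91 and the B cell difference 0.74, and without fisetin 5 those of macrophages, chemokines and complement were 0.26, 0.19 and 0.09. Without fisetin 6 those of macrophages, chemokines, complement and plasma cells were 0.57, 0.49, 0.24 and 2.05, and that of B cells was 1.55 without control 1. In each of these lists 0 members passed adjusted over the list alone and 0 over all genes by edgeR or DESeq2. Camera with its preset correlation called the macrophage (adjusted p = 1.72e-08), T and NK cell (6.45e-08), B cell (0.000168), dendritic cell (0.000257), plasma cell (0.000972) and chemokine lists (0.00255), each with an adjusted p = 0.733 with an estimated correlation. It also called the proximal tubule, thick limb, distal tubule, urothelial, senescence arrest, cell cycle, androgen-responsive and mineral metabolism lists, 23 of the 55 in all, and 0 with an estimated correlation, where the smallest adjusted p was 0.726.

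The remaining lists did not pass by fry or by score. Cell cycle genes were positive in 33 of 34 members and differed by 0.25 (exact permutation p = 0.17; Cenpe 0.55 ± 0.19, Tyms -0.12 ± 0.04). Androgen-responsive kidney genes differed by -0.47 (exact permutation p = 0.185; Timd2 -0.36 ± 0.13, Cyp4b1 -0.83 ± 0.41) and mineral metabolism genes by -0.20 (exact permutation p = 0.08; Slc20a1 0.37 ± 0.12, Slc34a3 -0.78 ± 0.39). The unfolded protein response differed by -0.04 (exact permutation p = 0.555), with the chaperone genes Calr (-0.18 ± 0.05) and Pdia6 (-0.14 ± 0.04) called over all genes by DESeq2 and not by edgeR. Heat shock genes differed by -0.12 (exact permutation p = 0.155; Hspe1 -0.27 ± 0.09, Hspa1b -0.24 ± 0.13) and immediate early genes by 0.06 (exact permutation p = 0.71; Atf3 0.38 ± 0.15, Dusp2 0.83 ± 0.32). Renin-angiotensin genes differed by 0.02 (exact permutation p = 0.8), with Ren1 at 0.02 ± 0.19, Ctsd at 0.14 ± 0.07 and Ace at -0.35 ± 0.17, and urothelial markers by -0.31 (exact permutation p = 0.335; Upk3b -0.42 ± 0.16, Upk3a -0.71 ± 0.35). Among markers of tissue that can come along with a kidney, adipocyte markers differed by 0.09 (exact permutation p = 0.92; 14 of 15 members positive, median fold change 0.5 and mean 0.48 in log2). Pck1, also a proximal tubule gene, was past the list's own adjustment and Pparg was at 0.35 ± 0.32. Erythrocyte markers differed by -0.05 (exact permutation p = 0.88; mean fold change positive at 0.10; Bpgm -0.15 ± 0.08, Alas2 0.31 ± 0.49). Skeletal muscle markers differed by 0.01 (exact permutation p = 0.965; median -0.22; Ttn 0.63 ± 0.27, Actn3 -0.22 ± 0.32) and lymphatic and neural markers by 0.03 with fry's direction down (exact permutation p = 0.59; Prox1 -0.34 ± 0.16, Mmrn1 0.32 ± 0.17).

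Whether fisetin's difference itself differed between the batches was asked with an interaction term. By edgeR 0 genes passed and 376 had an unadjusted p under 0.05, where chance gives 894. DESeq2 called 1, the pseudogene Pgam1-ps2, named after its values were seen, with 316 at an unadjusted p under 0.05. The batches themselves, compared with diet in the model, differed in 0 genes by edgeR (604 at an unadjusted p under 0.05) and 0 by DESeq2 (616).

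**Figure D4:**
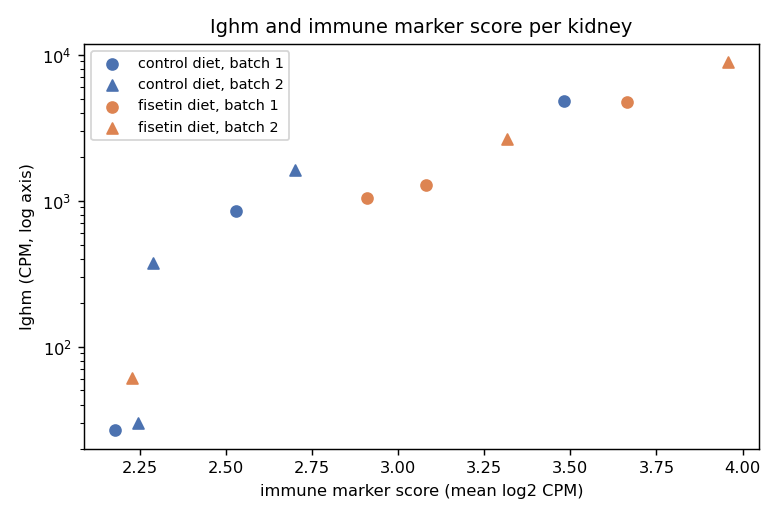
Ighm in CPM on a log axis against the mean immune marker score in log2 CPM, with each point a kidney, blue for control and orange for fisetin, circles for batch 1 and triangles for batch 2. Ighm ran from 26.65 to 8846 CPM, and kidneys of both diets lay at both ends.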

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

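The tests of principal against intercalated cell markers (and it without each library), of a clock phase index and of the hour of collection were chosen after the result was seen. Among 470 groups of 6 libraries examined (named genes, list scores and library measures by diet), 39 had a library whose gap to its nearest neighbour, divided by the group's range, was above Dixon's 95% critical value. Chance gives about 1 in 20 such groups. The gaps fell mostly on control 1 (15 as the highest and 4 as the lowest library) and fisetin 6 (5 and 10).

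In control 1, genes of antigen presentation and interferon response stood high among controls, with gap ratios of 0.727 for B2m, 0.814 for H2-Q4, 0.758 for Ciita, 0.743 for Tap1, 0.708 for Nlrc5 and 0.73 for Mx2. Flt3 (0.798) and Ccl12 (0.686) were high there too and Timd2 (0.778) was low. Its scores were high for antigen presentation (0.755), interferon response (0.683), chemokines (0.63), the ATF4 response (0.797) and ribosomal proteins (0.832), and low for heat shock (0.634) and thin limb markers (0.716). Control 1 also had 4.343% of its counts in 7SL RNA, against 2.677% in the next control (0.806), an FPKM over TPM ratio of 2.155 against 1.495 (0.876), and a first principal component of -26.34 against 16.22 (0.691).

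In fisetin 6, gap ratios among fisetin libraries were 0.668 for Npas2, 0.707 for Ren1, 0.641 for Cyp4a14 and 0.717 for Actg2, all on the high side. On the low side they were 0.714 for Cxcl2, 0.824 for Cxcl1, 0.675 for Atf3, 0.77 for Slc20a1, 0.746 for Pck1, 0.697 for Pmaip1, 0.66 for Plk2 and 0.691 for Ddx58. Its scores for tubular injury (0.793) and chemokines (0.661) were low. In fisetin 5, Aqp4 was low (0.696) and the glycolysis score high (0.727). Mdm2 (0.742) and the aryl hydrocarbon receptor score (0.657) were high in control 3, and Rtp4 (0.743) was low in fisetin 3.

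Interferon-response genes were 0.39 log2 higher with fisetin. More immune cells in the fisetin kidneys stay open as a cause. With the immune marker score as a covariate the difference was 0.223 (exact permutation p = 0.005, the smallest the arrangements can give), smaller than without it. That score averages lists of unlike spread (control SD 1.16 for B cells and 0.185 for dendritic cells). It may leave part of the immune cell share uncorrected, so the remaining difference does not decide. A single library is argued against, since the lowest difference with a library left out was 0.343, without fisetin 4. Of 100 regroupings of the libraries, only the real one, 1 in all, gave as many as 29 members adjusted over the list alone (highest other 21). The regroupings do not cover the choice of this list among 55. Over those lists its fry adjusted p was 0.0866, so chance could not be excluded. Its score had an adjusted p = 0.138, which says little, since several lists would have to come near the smallest p for any to pass. An effect of the diet may remain as a hypothesis, and an interferon response inside immune cells stays open.

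Collecting duct principal cell markers were lower with fisetin, by a difference of -0.48 log2. Fewer collecting ducts in the tissue taken stay open, since principal cell markers differed by a further -0.297 from intercalated cell markers (exact permutation p = 0.025; -0.20 and -0.40 in batches 1 and 2), but by -0.216 without fisetin 6, -0.245 without control 5 and -0.292 without control 6 (exact permutation p = 0.065, 0.07 and 0.06). A smaller share of all tubule cells stays open too, since the score differed from that of the other segments by only -0.16 (exact permutation p = 0.225; -0.10 and -0.22). Of 100 regroupings only the real one, 1 in all, gave as many as 11 members adjusted over the list alone (highest other 7). Over the 55 lists among which it was chosen its fry adjusted p was 0.128, so chance could not be excluded. Its score had an adjusted p = 0.138 although its exact permutation p was the smallest possible, so that value does not decide. A loss of tubule cells or the diet may each account for it, and they were not separated.

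Of 19 clock genes, 4 passed in both directions adjusted over the list alone and 0 over all genes by edgeR, and 1 passed without each of fisetin 2, 3 and 4 and control 2, 5 and 6, so chance stays open for that count, although fry for change in either direction had an adjusted p = 0.00829. An index took the mean of repressor and output genes minus that of genes whose messages follow the activator arm, Cry1 among them. It was 0.0836 ± 0.275 (SD, n = 6) with fisetin and -0.515 ± 0.204 (n = 6) with the control diet, a difference of 0.599 (exact permutation p = 0.005, the smallest the arrangements can give; 0.654 and 0.544 in batches 1 and 2). The index was chosen after these genes were seen and holds them, so its p restates that observation and does not test a shift in clock phase. The immune score accounted for little of the difference in the index. That difference was 0.582 with the immune score as a covariate (against 0.599 without it). A part of the immune cell share that the score may miss stays open here too. Kidneys collected at different hours and an effect of the diet or of feeding times cannot be told apart, because the labels give no hour, and a difference of 0.654 within batch 1 could come from either.

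For the counts over all genes that were above 0, chance could not be excluded. The 2608 genes at an unadjusted p under 0.05 were met by 7 of 100 (highest other 5529), the 153 genes by DESeq2 by 5 of 100 (highest other 2661), and the 2390 by limma-voom with quality weights by 10 of 100 (highest other 4741). Any regrouping meets a count of 0, so the 100 of 100 that did so for genes by edgeR (highest other 1), lists by fry (highest other 1), the batch term (highest other 1) and the interaction (highest other 3143) do not bear on chance. The 2661 genes by DESeq2 in another regrouping were several times the 153, so a grouping other than diet can give more calls. Each of the 4 other regroupings that met the 153 kept the diet of 8 of the 12 libraries, and what else they share was not tested. Regroupings were drawn without regard to batch. Of those 4, the regrouping with 568 genes held 3 libraries of each group in each batch, and those with 418, 2333 and 2661 did not.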

How the results depend on the processing

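The fits with the immune score as a covariate, without the small structural RNA genes, by DESeq2 without fisetin 5, fisetin 6 or control 1, and without robust estimation for the batch and interaction terms were chosen after the data were seen. The edgeR count of 0 genes for diet (2608 at an unadjusted p under 0.05) held with DESeq2 size factors, total count scaling, either filter on low counts, no batch term, batch 2 alone, no robust estimation, log2(TPM + 1), log2(TPM + 0.1), log2(FPKM + 1), the immune score and without the small structural RNAs. It was 153 by DESeq2 (91 higher, 62 lower) and 2390 by limma-voom with sample quality weights (1156 higher, 1234 lower, 149 of the 153 among them). It was 9 with surrogate variables (4 of the 153 among them) and 1 in batch 1 alone. Without each library in turn it ran from 0 to 70, with 1 without fisetin 4 and 70 without fisetin 6. DESeq2 called 63 genes without fisetin 5, 1713 without fisetin 6 and 614 without control 1, with 57, 153 and 149 of the 153 among them. The median log2 fold change of all genes was 0.0452 with total count scaling and highest, at 0.0758, by limma on log2(TPM + 0.1) with its own filter. The count of lists by fry was 0 and became 3 for change in either direction (p53 targets, interferon response, circadian clock), 23 by camera with its preset correlation, 0 by camera with an estimated one, and 2 without members that other lists hold (p53 targets and interferon response, adjusted p = 0.0399 for both). Without each library it ran from 0 to 2, with interferon response called without control 1 and, with p53 targets, without fisetin 6. No list score passed adjustment with total count scaling, z-scored members, labels permuted without regard to batch or any library left out. With so few arrangements no single list could have passed on its own. The batch count of 0 did not move in any setting run, and the interaction count of 0 was 1 by DESeq2. Of the values tried, 5138 for named genes kept their sign and side of the threshold, 403 kept their sign and passed, and 56 turned, and 712 list scores kept their sign and 58 turned. Depth limits the reading of low genes such as Cdkn2a. In simulated libraries, with each gene drawn independently, edgeR recovered 22.67% of 1.3-fold changes, so small changes go undetected in part. Counts of list members and of genes were close to the reported count in 142 of their settings, larger in 18 and smaller in 64. No paired analysis was possible because the labels give no replicate numbers, and those used here only name libraries in order.

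Signs of some log2 fold changes and score differences turned under some settings, and the cause was not tested. Not all were small, since Bank1, Cd37 and Prdm1 stood at 1.19, 0.91 and 0.64 in the main fit. With surrogate variables these were Col4a5 0.0034, Mtor 0.0086, Fn1 -0.13, Nphs1 0.10, mt-Cytb 0.13, Cd37 -0.097 and Pparg -0.19. With the immune score as a covariate they were Col4a5 0.0077, Fn1 -0.11, Nphs1 0.073, Bank1 -0.080, mt-Cytb 0.11, Cd37 -0.19, Prdm1 -0.051 and Pparg -0.21. limma-voom with sample quality weights gave Havcr1 0.027, Lcn2 0.073, Col1a1 0.13, Ren1 -0.16 and Alas2 -0.11. Batch 1 alone gave Col4a5 0.0025, Havcr1 0.035, Ren1 -0.11, Pparg -0.016 and Alas2 -0.17, and batch 2 alone Col1a1 0.13 and Actn3 0.14. DESeq2 without fisetin 6 gave Havcr1 0.017, Col1a1 0.048, Ren1 -0.22 and Alas2 -0.30 and without control 1 Col1a1 0.039. The log2 fold change of Pparg was -0.046 by DESeq2 without fisetin 5. On log2(TPM + 1), with and without its filter, Col1a1 0.051 and Tyms 0.00024 resulted. In all TPM fits 7SL RNA was kept in the scaling, at 40.34% (fisetin 5) to 53.1% (control 1) of all TPM. On log2(TPM + 0.1) the values were Col1a1 0.052 and Tyms 0.00012, and on log2(FPKM + 1) Col1a1 0.016. Total count scaling gave Col1a1 0.028. It also gave score differences above 0 for lists that were below it, namely mTOR pathway components 0.016, sterol biosynthesis 0.024, glycolysis 0.015, lysosome and autophagy 0.040, PPAR-alpha targets 0.022, basement membrane 0.019, aryl hydrocarbon receptor genes 0.024 and podocyte markers 0.022. The score difference of unfolded protein response was 0.0071.

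Leaving out each library in turn also turned some signs, with the library that gave each end of the range in parentheses. Log2 fold changes ran over Alas2 -0.29 (fisetin 6) to 0.55 (control 3), Col1a1 -0.087 (fisetin 4) to 0.051 (fisetin 6), Havcr1 -0.26 (fisetin 4) to 0.019 (fisetin 6), Lcn2 -0.21 (fisetin 2) to 0.022 (control 5), Pparg -0.043 (fisetin 5) to 0.50 (control 3) and Ren1 -0.21 (fisetin 6) to 0.094 (fisetin 5). Score differences ran over ATF4 amino acid response -0.027 (fisetin 5) to 0.13 (fisetin 6), PPAR-alpha targets -0.10 (fisetin 6) to 0.031 (control 3), adipocyte markers -0.45 (fisetin 5) to 0.51 (fisetin 3), aryl hydrocarbon receptor genes -0.10 (fisetin 6) to 0.068 (fisetin 4) and erythrocyte markers -0.37 (fisetin 6) to 0.23 (fisetin 5). They ran over fatty acid synthesis -0.24 (fisetin 5) to 0.051 (fisetin 4), immediate early genes -0.036 (fisetin 5) to 0.18 (fisetin 6), interstitial matrix -0.019 (fisetin 5) to 0.0999 (fisetin 6), lymphatic and neural markers -0.0019 (fisetin 2) to 0.078 (fisetin 3) and lysosome and autophagy -0.019 (fisetin 6) to 0.015 (fisetin 5) for other lists. For the rest they ran over mitochondrially encoded messages -0.19 (fisetin 6) to 0.0038 (fisetin 5), podocyte markers -0.076 (fisetin 6) to 0.020 (fisetin 5), renin-angiotensin -0.039 (fisetin 6) to 0.072 (fisetin 5), skeletal muscle markers -0.087 (fisetin 4) to 0.19 (fisetin 6) and sterol biosynthesis -0.054 (fisetin 6) to 0.027 (fisetin 4). Other score differences kept their sign but moved by over 1.5 times when a library was left out. These ran over mTOR pathway components -0.0429 (fisetin 6) to -0.0158 (fisetin 5), glycolysis -0.0595 (fisetin 5) to -0.00744 (fisetin 6), cytosolic ribosomal proteins 0.0114 (control 2) to 0.0669 (control 1), basement membrane -0.0451 (control 3) to -5.67e-05 (control 5), tubular injury and failed repair 0.0251 (fisetin 5) to 0.217 (fisetin 6) and senescence-associated secretory genes 0.0862 (fisetin 5) to 0.249 (fisetin 6). They ran over drug and flavonoid conjugation and transport -0.14 (fisetin 6) to -0.0204 (control 4), circadian clock 0.0238 (control 1) to 0.073 (control 3), cell cycle 0.141 (fisetin 5) to 0.369 (fisetin 6), unfolded protein response -0.065 (fisetin 5) to -0.00756 (fisetin 2), heat shock -0.162 (fisetin 4) to -0.0656 (fisetin 5) and mineral metabolism -0.287 (fisetin 6) to -0.116 (fisetin 5) for further lists. The rest ran over androgen-responsive kidney genes -0.668 (fisetin 6) to -0.266 (fisetin 5), endothelial markers -0.143 (fisetin 6) to -0.0332 (fisetin 5), mesangial and juxtaglomerular markers -0.105 (fisetin 6) to -0.00559 (fisetin 5), smooth muscle and pericyte markers -0.142 (control 3) to -0.0381 (fisetin 3), urothelial markers -0.497 (fisetin 1) to -0.093 (fisetin 3) and neutrophil and mast cell markers 0.0858 (control 3) to 0.262 (fisetin 6).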

Other observations

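Among immunoglobulin messages, Ighm, the heavy chain of IgM, differed by a factor of 332 between its lowest and highest library. It ran from 26.65 CPM in control 2 to 8846 CPM in fisetin 5, with 4838 in control 1 and 61.3 in fisetin 6. The most counted heavy chain variable gene was shared by control 1 and 6 (Ighv1-53, 26.9% and 19.6% of such counts), by fisetin 2 and 4 (Ighv1-82, 17.9% and 26.8%) and by fisetin 1 and 5 (Ighv1-19, 15.3% and 12.6%). It differed between the other 6 kidneys, with Ighv1-50 at 44% in control 3. Variable genes are near-identical, so these shares are uncertain.

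Across the 12 kidneys, over 5 relations computed, plasma cell scores followed T and NK cell scores (Pearson r = 0.954, permutation p = 1e-05, the smallest the permutations can give, adjusted p = 5e-05; Spearman rho = 0.965, permutation p = 1e-05, adjusted p = 5e-05). Without the 2 kidneys farthest from the median r was 0.954, and it was 0.953 and 0.954 in batches 1 and 2. They followed macrophage scores less closely (r = 0.729, permutation p = 0.00825, adjusted p = 0.0206; rho = 0.713, permutation p = 0.0112, adjusted p = 0.028; 0.574 without 2 kidneys; 0.747 and 0.737 in the batches). With proximal tubule scores r was -0.62 (permutation p = 0.0333, adjusted p = 0.0555; rho = -0.671, permutation p = 0.0196, adjusted p = 0.0327; -0.418 without 2 kidneys, on which it rests in part; -0.734 and -0.57 in the batches). All 5 relations pooled both diets, between which the plasma cell score differed by 1.44 and the proximal tubule score by -0.275. No relation was computed within a diet. Matrix scores (r = 0.432, permutation p = 0.16, adjusted p = 0.2; rho = 0.531, permutation p = 0.0801, adjusted p = 0.1; 0.26 without 2 kidneys; 0.422 and 0.41) and adipocyte scores (r = 0.242, permutation p = 0.441, adjusted p = 0.441; rho = 0.266, permutation p = 0.404, adjusted p = 0.404; 0.0988 without 2 kidneys; -0.186 and 0.517) gave no adjusted p under 0.05.

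The first principal component held 46.11% of the variance and ran from -59.97 in fisetin 5 and -44.36 in fisetin 1 to 40.53 in fisetin 6. With 2 surrogate variables in the model, 9 genes passed, named here after their values were seen. Vnn1, a pantetheinase (log2 fold change 0.41, adjusted p = 0.00456), Ephx1 (0.48, adjusted p = 0.00626), Aqp6, a channel of intercalated cells (0.41, adjusted p = 0.0115), and Gsta2 (0.37, adjusted p = 0.0132) were higher with fisetin. Cxcl14 (-0.46, adjusted p = 0.0121), Cbs (-0.44, adjusted p = 0.0448), the arginine transporter gene Slc7a1 (-0.32, adjusted p = 0.0448), Ptger1 (-0.68, adjusted p = 0.0455) and Fads2 (-0.24, adjusted p = 0.0473) were lower. By DESeq2 the smallest adjusted p, 4.41e-05, belonged to Slitrk1 and to Aldh1a3, a retinaldehyde dehydrogenase gene (log2 fold change -1.48 ± 0.25 SE), also named after its values were seen.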
